A study of Mus musculus with 2 samples.

How the data were processed

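DNase-seq maps open chromatin by cutting nuclei with the enzyme DNase I and sequencing the cut ends. It was applied here to the cerebellum of male mice of strain B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ, at 25 days of age. The labels give 1 group of 2 biological replicates with no treatment, so the comparison the design implies is between the replicates. Each library carries its own animal number in the labels, while both carry 1 shared donor identifier. The spread between the replicates is therefore reported as the spread between these 2 libraries.

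For each library the authors deposited 2 peak lists, a footprint list and a list of false discovery rates, all on the mouse build mm10 per the labels. A deposited text file names each list by its output type and records that each was made per library from the filtered alignments, with no pooling of replicates. The aligner, the peak caller, the footprint caller, their versions and their thresholds are not given in the sources used here.

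The deposited peak lists hold 1 signal value per peak, which is the authors' own value, and its scale is not stated. All signal values of a library were whole multiples of a smallest step (100% within 0.05 steps), 0.00629 in replicate 1 and 0.00277 in replicate 2, as a count divided by a library's depth would be. The inverse of the step, 2.27 times larger in replicate 2, was used as the relative depth of the libraries, which assumes that 1 step stands for 1 read in both. The deposited false discovery rates (q-value, per run of bases) were listed only below 0.05. Every peak of the longer list of each library overlapped such a position, and every peak of the shorter list overlapped a position at 0.001 or below. The deposited footprint lists hold intervals, and their other column holds the constant 0.01 in every line, so footprints were not ranked.

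The analysis had been planned for counts of DNase I cuts in the lists of false discovery rates. Those lists held rates and no counts, so the authors' peak signal was used in place of cuts throughout, as the plan allowed. Wherever a count of 100 cuts had been planned as a minimum, 100 steps were required. Total read counts are not used here, so intervals on shares of peaks cover the number of peaks and not the depth of sequencing.

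Peaks and footprints on chromosomes 1 to 19, X and Y were used. Coordinates were compared with the reference assembly GRCm38.p6, whose chromosome lengths contain every coordinate of the deposited lists, and genes were taken from GENCODE M21 (21853 protein-coding genes). The longer peak list of each library was the main list. Overlaps were computed with bedtools 2.31.1 and counted from 1 shared base. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with random seed 1. Coordinates are printed counting from 1.

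Peaks of each library were split into 10 strength classes by signal. Overlapping peaks of both libraries were merged into a union, and the log2(signal + 1) of both libraries was compared across it, a library with no peak counting as 0. A peak was a promoter peak when its centre lay within 1000 bp of a transcription start site of a protein-coding gene. The remaining peaks were assigned to exons or introns of protein-coding genes or to intergenic sequence, and are called distal. Intergenic here means outside protein-coding genes, and such sequence can hold genes of other kinds. The promoter signal of a gene was that of the strongest peak overlapping the window of 1000 bp on each side of any start site of its protein-coding transcripts, and 0 where none was listed. Distal peaks of a gene were those centred in its body or within 20 kb of it, per 10 kb.

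The 18 gene lists, the 25 consensus motifs, the tests and most of the other settings were fixed before the data were examined. All 278 list entries were found in the annotation. Genes are not replicates, so no p-value was computed for a list. Instead the median of a list was placed among 10000 random lists of equal size, matched on the decile of promoter CpG content (observed over expected) for promoter signal and on the decile of gene length for distal peaks. A list is called high at percentile 95 or above and low at percentile 5 or below. With 18 lists, 1.8 would lie beyond these percentiles by chance. The log2 ratio of the replicates at promoters was placed in the same way among random lists matched on the decile of mean promoter signal.

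Motif matches were exact, on both strands, in footprints widened by 5 bases on each side, and were divided by the matches per kb in the rest of the same peaks. Lengths in kb here count only start positions at which the whole motif fits. The interval of each ratio is the exact Poisson 95% interval of the count in footprints. It leaves out the error of the background count, and an interval from both counts was added after the data were examined. Shares carry Wilson 95% intervals, and the ratio of the X chromosome to the autosomes a bootstrap interval from 1000 resamples of peaks.

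Genes were named by a rule. It takes for each list the 2 members with the highest and the 2 with the lowest mean promoter signal. Over all protein-coding genes it takes the 10 with the most distal peaks found in both replicates, the 10 strongest distal peaks found in both, and the 10 promoters with the largest fold between the replicates in each direction among those with at least 100 steps in 1 replicate. It also takes the 5 promoters with the most footprints shared by both replicates. Some genes that the rule takes are not reported here. Hoxa10, Hoxd1, Skor2, Tal1, the Zic and other genes of highest peak density and the genes of the X and Y pairs were named after their values were seen.

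The steps were tested on simulated data. The step was recovered for 100% of 50000 simulated values of each library, and 100% of the planted overlaps among 1000 regions were found with 0 false ones. Of simulated lists drawn from the 21853 genes without a shift, 0% lay at percentile 95 or above and 2.5% at percentile 5 or below. These lists were few and came only from genes of higher promoter CpG content. Lists with a median of 0 were thus not tested. A shift of 1 SD put 77.5% of lists at percentile 95 or above, and a shift of 2 SD put 100% there. The motif search found all planted matches. In the GC matching, 0.327% of a simulated difference set by GC content and 99.7% of one set by location remained.

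Alternatives tried were the shorter peak list, the stronger 50% of peaks, overlap of at least 50% of both peaks or footprints and equal list lengths. Others were pseudocounts of 0.1 and 5, thinning of the deeper library, scaling by the median ratio, promoter windows of 500 and 2500 bp, flanks of 50 kb or none, unmatched random lists, other peak sets for the X chromosome, other motif backgrounds and leaving out each replicate. Single gene starts, the shorter peak list for distal peaks and footprints, distal peaks for the X chromosome, promoter peaks for motifs, a motif background from peaks with a footprint, and matching on CpG content for the log2 ratio of the replicates were added after the data were examined. The folds between overlapping peaks at the named promoters were also computed after their values were seen.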

Results

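Open chromatin was profiled by DNase-seq in the cerebellum of male 25-day-old mice of the cross B6CASTF1/J, in 2 biological replicates. The longer deposited list held 144149 peaks in replicate 1 and 247161 in replicate 2, covering 29.8 and 45.1 Mb. Peaks had a median width of 200 bp in replicate 1 and 180 bp in replicate 2. The median signal of a peak was 0.691 (quartiles 0.358 and 1.77) in replicate 1 and 0.413 (quartiles 0.216 and 1.12) in replicate 2. By the size of the smallest signal step, replicate 2 was 2.27 times deeper, if 1 step stands for 1 read in both. With 1 group and no treatment, values are given for each replicate and no test between groups was possible.

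The first question was how far the replicates shared their open sites. Promoters of 14318 of the 21853 protein-coding genes (65.5%) carried a peak in both replicates, 48 genes had one only in replicate 1 and 1258 only in replicate 2. Neither replicate listed a promoter peak for 6229 genes. Among genes used by every cell, the ribosomal protein gene Rplp0 had a promoter signal of 29.3 in replicate 1 and 31.2 in replicate 2, and the elongation factor gene Eef2 one of 18.2 and 40.4. Of the promoter peaks, 91.8% of replicate 1 and 71.4% of replicate 2 overlapped a peak of the other replicate, against 89.1% and 49.9% of the intergenic peaks.

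Over all peaks, 90.3% of replicate 1 (Wilson 95% interval 90.1 to 90.5) and 53.2% of replicate 2 (53.02 to 53.4) overlapped a peak of the other replicate. After a shift of 100 kb, 5.96% and 3.53% did. Peaks of the strongest of the 10 classes by signal were shared at 99.9% in replicate 1 and 98.5% in replicate 2, and those of the weakest class at 60.5% and 8.56%. Replicate 1 had 13985 peaks with no partner and replicate 2 had 115636. In the strongest class, 21 peaks of replicate 1 and 373 peaks of replicate 2 had no partner in the other list. Of these, 21 and 372 lay on positions that the other library listed below a false discovery rate of 0.05, and 18 and 333 lay at promoters. Of all peaks with no partner, 28.2% and 11.7% lay on such positions. The unequal lengths of the lists bear on these shares.

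**Figure D1:**
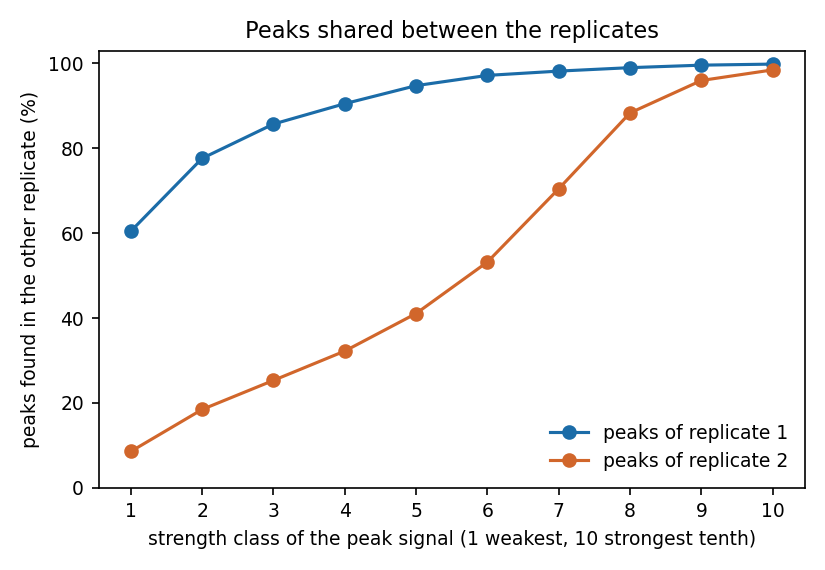
Share of peaks (percent) that overlapped a peak of the other replicate, by strength class of the peak signal from 1 (weakest) to 10 (strongest), each of about equal size, for replicate 1 (blue) and replicate 2 (orange). Sharing was 99.9% and 98.5% in the strongest class and 60.5% and 8.56% in the weakest.

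Signal at individual promoters was compared next. Across the 14111 genes with a promoter peak in both replicates and at least 100 steps in 1 of them, the median log2 ratio of replicate 2 to replicate 1 was 0.78 (quartiles 0.50 and 1.05). Promoters of granule neuron genes lay below this, at a median of 0.50 over 18 genes, the 0.71 percentile among random lists of like signal. Housekeeping promoters had a median of 0.61 (percentile 8.67) and activity-regulated promoters 0.61 (percentile 7.6), Purkinje cell promoters 0.86 (65.7) and Bergmann glia and astrocyte promoters 0.69 (32.5). Among random lists matched on CpG content in place of signal, the percentiles were 0.66 for granule neuron, 3.54 for housekeeping and 5.14 for activity-regulated promoters. Neither set of random lists was matched on GC content. The median log2 ratio of promoter peaks ran from -0.15 in the lowest of 10 GC classes to 1.00 in the highest. Whether GC content accounts for the place of these lists was not tested.

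The promoter signal of a gene is that of the strongest peak touching its window, so the 2 values can come from different peaks. The promoters furthest above in replicate 1 were those of Mst1 with signals of 8.26 and 0.457 (18.1-fold), of Efcab9 with 5.73 and 0.573 (9.998-fold) and of the keratin gene Krt24 with 3.49 and 0.416 (8.41-fold). In these 3 the replicate 2 peak at the same site lay outside the window, with signals of 15.99, 11.1 and 2.65, so the folds arise at the window edge. The same held for Mybpc3 (6.11 in replicate 1 and 6.97 at the same site in replicate 2), Hist1h2bh (2.17 and 1.69), Best1 (0.654 and 0.551) and Acta1 (1.14 and 1.32). Runx3 and Fgfr1op were 3.40-fold and 6.84-fold higher in replicate 1 between overlapping peaks. For Brsk2, a kinase gene of neurons, the values of 14.3 and 3.62 belong to separate peaks.

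In the other direction, the promoter of Naif1 on chromosome 2 had signals of 0.396 in replicate 1 and 30.3 in replicate 2 (76.5-fold). Its peak in replicate 2, from 32451421 to 32451620, overlapped a peak of replicate 1 outside the window with a signal of 13.6, so the fold at the site was 2.23. That of Zc3h4 was 1.71 in the same way. Dtnbp1 and Neurl1b were 4.79-fold and 4.68-fold higher in replicate 2 between overlapping peaks. Gm11168 and Gm10719 on chromosome 9 were 15.9-fold and 16.1-fold higher in replicate 2 between overlapping peaks. Their peaks held sequences of 36 bases found 71 and 35 times in the reference. The peaks of Gigyf1 (1.72), Sapcd1 (1.12), Spred3 (4.30) and Tldc2 (0.476) in replicate 2 overlapped no peak of replicate 1, and those of Gigyf1, Sapcd1 and Tldc2 did not touch any position below the false discovery limit there.

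Across the 252915 union peaks, of which 49.8% were listed in both replicates, log2(signal + 1) of the replicates had a Pearson correlation of 0.934 and a Spearman correlation of 0.718. These values are across peaks, which are not independent replicates. On that scale 2.73% of union peaks differed by more than 2-fold. The share was 49.5% with a pseudocount of 0.1 and 0.218% with a pseudocount of 5, so it depends on the pseudocount. Among the 74069 shared peaks with at least 100 steps in both replicates, the median log2 ratio of replicate 2 to replicate 1 was 0.389 with no pseudocount. Of these peaks 6.25% lay more than 2-fold from that median ratio, a centred measure unlike the shares above.

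Open sites were then placed on the gene annotation. Promoters held 20.6% of peaks in replicate 1 (20.4 to 20.8) and 15.7% in replicate 2 (15.5 to 15.8), against 2.44% of the assembled genome, 8.44 and 6.42 times its share. Exons held 5.17% and 6.43%, introns 39.5% and 41.3%, and intergenic sequence 34.8% and 36.6%, against 60.1% of the genome for the latter. In the strongest class of peaks 58.3% and 49.1% lay at promoters, and in the weakest 8.40% and 3.46%. The promoter share was 14.6% and 10.7% with a window of 500 bp.

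The 10 genes with the most distal peaks in both replicates were long as annotated, from 422 kb (Rbfox3) to 4435 kb (Gm20388). Gm20388, a predicted gene on chromosome 8, held 499, and Fgfr2, a fibroblast growth factor receptor gene, held 223. The RNA-binding protein genes Rbfox1 and Rbfox3, the second of which encodes the neuronal marker NeuN, held 131 and 122. The cell adhesion genes Ntm, Lsamp, Nrxn3 and Kirrel3 held 120, 107, 100 and 93, and Camta1 and Nav2 held 102 and 97. Per 10 kb, Rbfox3 had 2.64 and Lsamp 0.478.

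Of the 10 strongest distal peaks found in both replicates, the first lay in intergenic sequence of chromosome 8, from 20424741 to 20424940, with signals of 34.7 and 52.7. The next lay in an intron of Vps37c on chromosome 19, from 10709481 to 10709680 (34.6 and 52.8). Others were in intergenic sequence of chromosome 8 from 20122145 (36.2 and 50.3), chromosome 17 from 39846781 (53.6 and 30.1), chromosome 5 from 25529581 (29.7 and 48.5) and chromosome 7 from 34234081, 3.87 kb from the start of Gpi1 (29.6 and 39.5). The peak from 123461901 on chromosome 9 lay in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase gene (36.5 and 30.9). The remaining peaks were 1.75 kb from the start of Tle3 on chromosome 9 (26.6 and 39.8), from 149006801 on chromosome 5 (23.4 and 44.5) and 17.7 kb from the start of Nacc2 on chromosome 2 (24.6 and 42.1). Sequences of 36 bases in the peak from 20122145 and in that of Lars2 occur 5 and 7 times in the reference. Those in the first peak and in the peak on chromosome 17 occur 4 and 2 times. Peaks called intergenic lie outside protein-coding genes, and genes of other kinds at these sites were not searched.

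The X chromosome, of which males carry 1 copy, was set against the autosomes. Promoter peaks on the X had a median signal of 0.867 in replicate 1 and 0.807 in replicate 2, against 1.52 and 1.32 on the autosomes. The ratio was 0.570 (bootstrap 95% interval 0.512 to 0.653) in replicate 1 and 0.611 (0.538 to 0.683) in replicate 2. The X carried 23.4 and 39.6 peaks per Mb, the Y 0.624 and 1.70, and chromosome 11, the densest, 85.0 and 146. How well reads could be placed on each chromosome was not examined, so these numbers do not measure openness alone.

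Promoters of the cell types of the cerebellum were compared with random promoters of like CpG content. Among 18 granule neuron genes, all 18 had a promoter peak in both replicates, against 85.9% of random genes. The highest were Cbln3, which encodes a cerebellin of granule cells, with 18.3 and 24.8, and the transcription factor gene Neurod1 with 14.8 and 20.7. The lowest were Zic4 with 3.39 and 4.83 and the GABA-A receptor subunit gene Gabra6 with 4.34 and 2.87. Of 18 Purkinje cell genes 15 had a promoter peak in both, against 75.9% of random genes. The Purkinje cell genes were led by the calcium channel gene Itpr1 with 12.8 and 16.5 and the LIM homeobox gene Lhx1 with 10.3 and 15.4. Pcp2 and Ppp1r17 had none in either replicate, and Skor2 had one only in replicate 2.

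Against random lists matched on CpG content, the median of granule neuron promoters stood at percentile 66.3 and that of Purkinje cell promoters at 10.9, neither beyond the limits. Inhibitory interneuron promoters were low (percentile 0.03, 11 of 13 with a peak in both against 91.9% of random genes). Among them Nxph1 had 1.43 and 1.99, Tfap2b had 0.365 and 0.271, and Pax2 was listed only in replicate 2 at 0.529. Promoters of unipolar brush cells and cerebellar nuclei were also low (percentile 0.07, 8 of 10 against 86.6% of random genes). These promoters ran from Eomes with 2.29 and 4.82 and Slc17a6 with 1.82 and 2.16 to Lmx1b, listed only in replicate 2 at 0.346, and Sln, listed in neither. Granule cell progenitor and cell cycle promoters were low at percentile 2.34 with 13 of 14 listed in both (89.4% of random genes). Among them Top2a had 13.1 and 6.51, Ccnb1 7.05 and 12.4, Dcx 0.434 and 0.521, and Ccnd2 0 and 0.748.

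All 14 Bergmann glia and astrocyte genes had a promoter peak in both replicates, against 66.2% of random genes (percentile 12.3). The highest were Fabp7 with 3.97 and 7.28 and the glutamate transporter gene Slc1a2 with 3.47 and 5.84. The lowest were Aqp4 with 0.289 and 0.457 and Gfap with 0.283 and 0.424. Oligodendrocyte promoters were listed in both for 9 of 15 genes (percentile 29.9), against 55.7% of random genes. The myelin gene Mbp had 2.55 and 5.99 and its regulator Myrf 1.51 and 4.65, while Mobp was listed in neither. Of 14 microglia genes 2 were listed in both (percentile 29.3), among them the complement gene C1qc with 1.87 and 3.66, and Tmem119 and Tyrobp were listed in neither. Of 14 endothelial and mural genes 5 were listed in both (12.9), against 58.2% of random genes. Among them Slc2a1 had 6.04 and 13.5 and Erg 0.735 and 1.46, while Ly6c1 and Pecam1 were listed in neither. Choroid plexus and ependyma genes were listed in both for 6 of 10 (7.42), against 64.2% of random genes. Of these lists' last members, Foxj1 had 5.40 and 9.70 and Enpp2 1.55 and 2.70, while Folr1 and Kcne2 were listed in neither.

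Activity-regulated genes, which neurons switch on when stimulated, had a promoter peak in both replicates in 16 of 16 cases (percentile 60.5), against 94.7% of random genes. Jun had 22.1 and 28.3, Dusp1 17.1 and 32.6, Egr2 4.29 and 6.35, and Egr3 2.57 and 3.33. Housekeeping promoters were the only high list of the 18 (percentile 99.9, 18 of 18 against 92.7% of random genes). Hprt at 4.45 and 8.25 and Gusb at 1.43 and 2.16 were the lowest housekeeping members.

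Lists of other tissues and regions were compared in the same way. Of 38 Hox genes, which pattern the body axis behind the cerebellum, 4 had a promoter peak in both replicates against 89.3% of random genes of like CpG content (percentile 0). These were Hoxa7 with 3.32 and 6.89, Hoxc5 with 0.729 and 1.17, Hoxa10 with 0.585 and 1.18 and Hoxd1 with 0.415 and 0.654, while 26 Hox genes, among them Hoxd4 and Hoxd8, were listed in neither. Of 15 forebrain genes 9 were listed in both against 95.6% of random genes (percentile 0), with the dopamine receptor gene Drd1 at 3.16 and 6.80 and Nkx2-1 in neither. Of 10 pluripotency and germ line genes only Dazl was listed in both, at 6.83 and 13.0 (percentile 0.37). Sycp3 had 0.285 in replicate 2 alone, and Zfp42 and Zp3 were listed in neither. In replicate 2 alone 11 of 38 Hox genes (94.1% of random genes), 14 of 15 forebrain genes (98.5%) and 5 of 10 germ line genes (75.9%) were listed, so the size of these deficits depends on the replicate. With a window of 2500 bp, 10 of 38 Hox genes (91.0% of random genes), 10 of 15 forebrain genes (96.4%) and 2 of 10 germ line genes (71.9%) were listed in both.

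Liver genes were listed in both replicates in 2 of 16 cases (percentile 42.3), Apob at 1.80 and 3.03 and Apoc3 at 0.629 and 0.792, with Tat and Tdo2 in neither. Skeletal muscle genes were listed in 3 of 13 (21.4), Mylpf at 7.62 and 14.9, Tnnt3 at 0.761 and 0.997 and Acta1 at 1.14 and 0.468, with Myh1 and Myh2 in neither. Blood genes were listed in 3 of 12 (21.9), among them Mpo at 0.534 and 1.02 and Tal1 at 0.911 and 0.587, with Hbb-bs and Ms4a1 in neither. The medians of microglia, liver and blood genes were 0 and those of their random lists at or near 0, so these 3 percentiles carry little information. Listed in both were 14.3% of microglia, 12.5% of liver, 25.0% of blood and 23.1% of muscle genes, against 34.3%, 25.3%, 39.1% and 53.9% of random genes. With a window of 2500 bp these shares were 28.6%, 25.0%, 33.3% and 53.8%, against 41.7%, 33.1%, 44.5% and 59.4%. With 500 bp that of muscle genes was 7.69% against 51.2%, so the size of the deficits depends on the window. In replicate 2 alone 10 of 13 muscle genes were listed (63.3% of random genes), 11 of 14 endothelial and mural genes (67.3%), 8 of 10 choroid plexus and ependyma genes (71.7%) and 13 of 13 interneuron genes (96.0%), so for these lists the side on which the share lies depends on the replicate. Without matching on CpG content, the low calls ended for interneuron (percentile 26.8), unipolar brush cell (24.6), forebrain (16.8), progenitor (57.1) and germ line promoters (5.195), while those of Hox genes stayed.

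Distal peaks around the same genes were counted next. Granule neuron genes had a median of 2.73 distal peaks per 10 kb in replicate 1 and 5.31 in replicate 2. The mean of the replicates, 3.84, was 5.80 times that of random lists matched on gene length (percentile 100), and 16 of 18 members had at least 2 times the density of the median gene in both replicates. Neurod1 had 12 and 28 distal peaks, Cbln3 9 and 25, Zic4 44 and 62, and Gabra6 9 and 14. Activity-regulated genes came second with 2.17 per 10 kb, 3.58 times random (percentile 100, 12 of 16 members at 2 times or more), Dusp1 having 12 and 53 and Jun 5 and 10. The size of these ratios depends on the window. They were 11.9 and 40.3 within gene bodies alone, where random lists for the second had a median of 0.113 per 10 kb, and 4.07 and 2.42 with flanks of 50 kb.

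Progenitor and cell cycle genes had 1.34 per 10 kb (2.07 times random, percentile 99.4), with Top2a at 5 and 13 and Ccnd2 at 5 and 15. Bergmann glia and astrocyte genes had 1.14 (1.74 times, 97.3), with Slc1a2 at 19 and 22 and Gfap at 5 and 15. Housekeeping genes had 1.12 (1.79 times, 97.4) and microglia genes 1.10 (1.72 times, 96.1). The calls for housekeeping and microglia genes ended within gene bodies alone (percentiles 81.7 and 61.2) and without replicate 2 (94.9 and 94.4), that of housekeeping genes also with the shorter peak lists (86.3), and those of microglia and progenitor genes with flanks of 50 kb (87.6 and 93.1). Windows of 20 kb also take in peaks of neighbouring genes.

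The other 12 lists were not called. Purkinje cell genes had 0.823 distal peaks per 10 kb (percentile 79.3), with Itpr1 at 22 and 35 and Pcp2 at 2 and 3. Unipolar brush cell and nuclear genes had 0.950 (85.5), interneuron genes 0.755 (61.8), oligodendrocyte genes 0.760 (68.4), forebrain genes 0.786 (72.6) and muscle genes 0.752 (72.6). Blood genes had 0.666 (57.1), endothelial genes 0.554 (24.5), liver genes 0.547 (36.5), Hox genes 0.523 (38.4), choroid plexus genes 0.491 (18.8) and germ line genes 0.327 (10.9). Calls appeared for unipolar brush cell genes without replicate 2 (98.5), oligodendrocyte genes with flanks of 50 kb (95.9) and muscle genes within gene bodies (98.4).

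**Figure D2:**
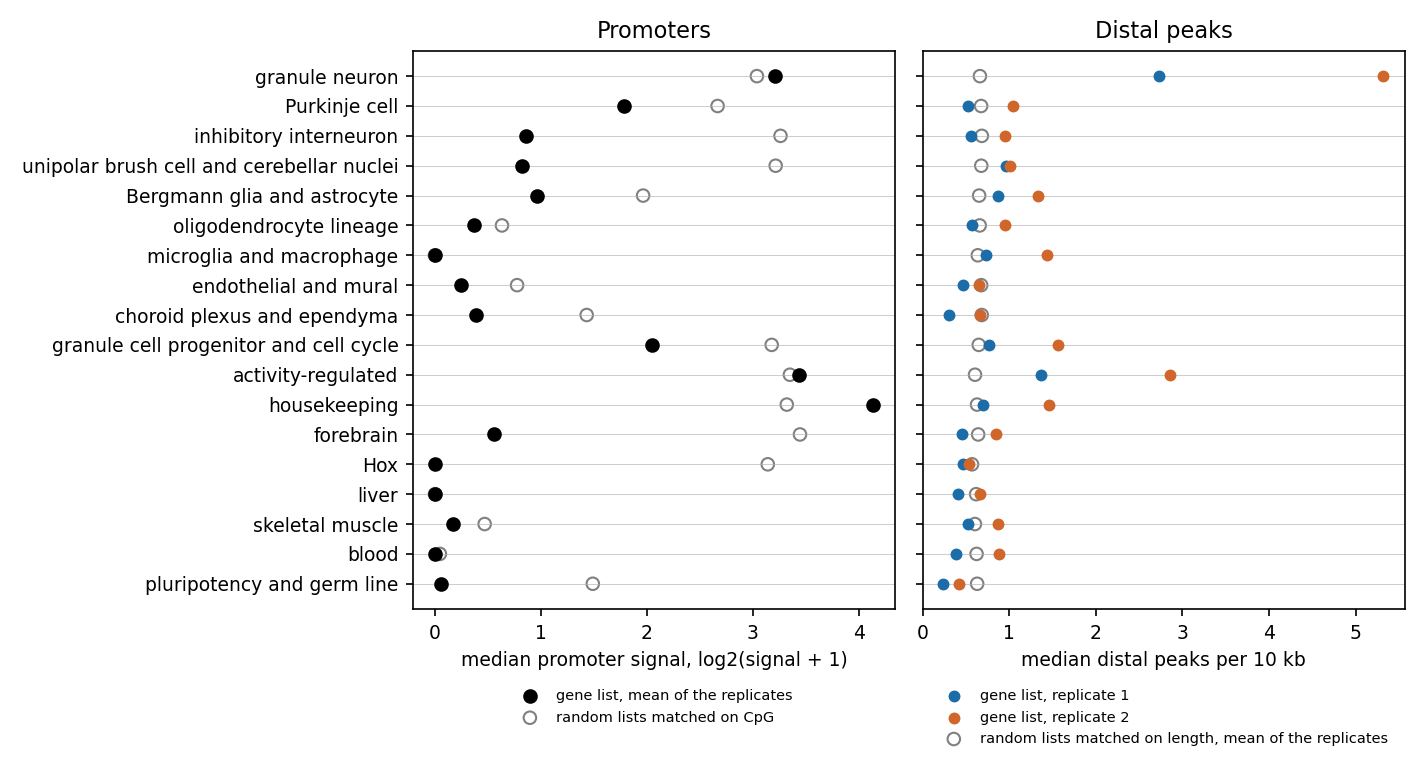
Left, median promoter signal of each gene list as log2(signal + 1), mean of both replicates (black), with the median of random lists matched on CpG content (open). Right, median distal peaks per 10 kb in replicate 1 (blue) and replicate 2 (orange), with the median of random lists matched on gene length (open). Granule neuron genes had the most distal peaks of the 18 lists, 2.73 and 5.31 per 10 kb.

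Footprints are short stretches protected from DNase I inside open chromatin, as bound proteins leave them. The promoters with the most footprints shared by both replicates were those of Ank2, a gene of the neuronal membrane skeleton, with 47 footprints of replicate 1 and 44 of replicate 2, and of Gse1 with 44 and 41. Ppp2r3d had 43 and 41, the transcription factor gene Tcf4 39 and 36, and Camta1 37 and 35. These counts cover all start sites of a gene, which number 44 for Tcf4 and 4 for Gse1. Promoter peaks carried 11.2 and 14.6 footprints per kb, intronic peaks 9.63 and 12.7. A footprint was found in 73.4% of promoter and 77.8% of intronic peaks in replicate 1, and in 85.2% of both in replicate 2. Footprints per kb rose from 0.537 and 3.34 in the weakest of the 10 strength classes to 21.6 and 22.4 in the strongest. The promoter share of peaks was also higher in the strongest class. Whether promoter and intronic peaks of equal strength differ in footprints per kb was not tested.

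The authors' lists held 343613 footprints in replicate 1 and 703887 in replicate 2, with median widths of 10 and 11 bp. Peaks contained 86.6% and 82.0% of them. A footprint was found in 73.9% of the peaks of replicate 1 and 82.5% of those of replicate 2, with means of 2.09 and 2.36 per peak. Of the footprints of replicate 1, 73.6% (73.4 to 73.7) overlapped one of replicate 2, and 31.8% (31.7 to 31.9) the other way. At 50% overlap of both footprints these shares were 39.5% and 19.3%. Within peaks listed in both replicates, 76.0% and 48.3% overlapped, against 44.5% and 31.0% after a shift of 40 bp.

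**Figure D3:**
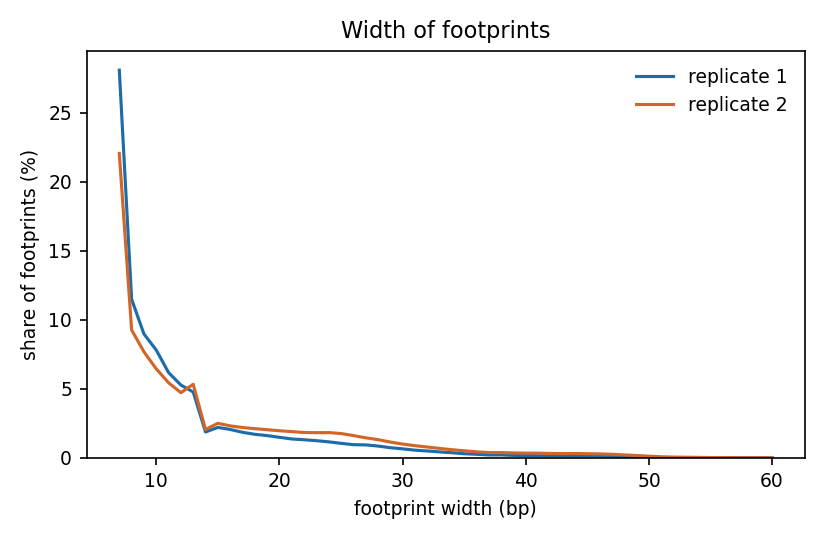
Share of footprints (percent) by width in bp for replicate 1 (blue) and replicate 2 (orange). The narrowest width, 7 bp, held 28.1% and 22.04%, and widths of 20 bp or more held 16.2% and 25.9%.

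Consensus motifs of transcription factors were then searched in footprints. Matches of CTCF, the factor that bounds chromatin loops, were 36.7 times (35.3 to 38.0) as dense in footprints as in the rest of the peaks in replicate 1 and 71.2 times (69.0 to 73.5) in replicate 2. The motif of the ZIC family, which acts in granule cells, had ratios of 16.1 (15.1 to 17.2) and 24.5 (23.3 to 25.7), and the NFI dimer 7.89 (6.50 to 9.49) and 24.1 (21.6 to 26.7). The E-box of NEUROD and ATOH1, factors of granule neurons and their progenitors, had ratios of 2.92 and 2.42 from 7685 and 12452 matches, and of 1.47 and 1.34 in promoter peaks. The size of these ratios depends on the choices made, beyond the intervals given. With no bases added to the footprints they were 99.2 and 178 for CTCF, 41.4 and 55.3 for ZIC and 18.2 and 57.9 for the NFI dimer. Without added bases only footprints at least as long as the motif count, 13, 10 and 15 bp in that order. The median footprint width was 10 bp in replicate 1 and 11 bp in replicate 2. With background only from peaks with a footprint the ratios were 54.0 and 127, 25.6 and 37.3, and 17.4 and 38.5 in the same order.

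Of the 25 motifs, 13 had a ratio of 2 or more in both replicates, and none of the 5 contrast motifs (HNF1, HNF4, GATA, PU.1 and p53) did against the rest of the peaks. NRF1 had 57.5 and 45.1, YY1 16.1 and 12.5, CREB 10.2 and 10.01, and the E-box of USF 9.75 and 10.7. RFX had 16.8 and 58.8 from only 15 and 4 matches outside footprints, with intervals from both counts of 9.18 to 32.4 and 22.1 to 221. ETS had 6.60 and 4.11, SP and KLF 5.36 and 5.85, EGR 4.88 and 5.82, and REST 3.597 and 3.91. NFY had 2.63 and 1.67, and the TCF E-box 1.23 and 1.22, the latter turning to 0.587 and 0.726 in promoter peaks. Outside promoters NRF1 had 21.6 and 14.8, YY1 9.83 and 3.78, CREB 4.12 and 5.25, USF 2.51 and 4.23, SP and KLF 2.97 and 3.72, ETS 2.89 and 1.76 and NFY 1.38 and 1.03.

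Ratios were below 1 in both replicates, intervals included, for 6 motifs. These were the homeodomain motif of LHX and EN (0.329 and 0.609), RORA (0.406 and 0.561), MEF2 (0.518 and 0.556), AP-1 (0.829 and 0.789), GATA (0.417 and 0.490) and p53 (0.528 and 0.572). SOX had 0.767 and 0.894 and PU.1 0.805 and 0.683, each with 1 interval that included 1, and HNF4 had 1.53 and 1.04. HNF1 had 0 and 1 matches in footprints, too few for a ratio. Set against the reversed motif in the same footprints, matches of MEF2, RORA, AP-1 and p53 were 1.84 to 5.17 times as frequent, so the direction for these motifs depends on the background. On that scale 3 of the 5 contrast motifs also passed 2 in both replicates, HNF4 (5.57 and 3.34), PU.1 (4.63 and 2.57) and p53 (4.91 and 4.68), so the reversed motif does not set the contrast motifs apart.

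**Figure D4:**
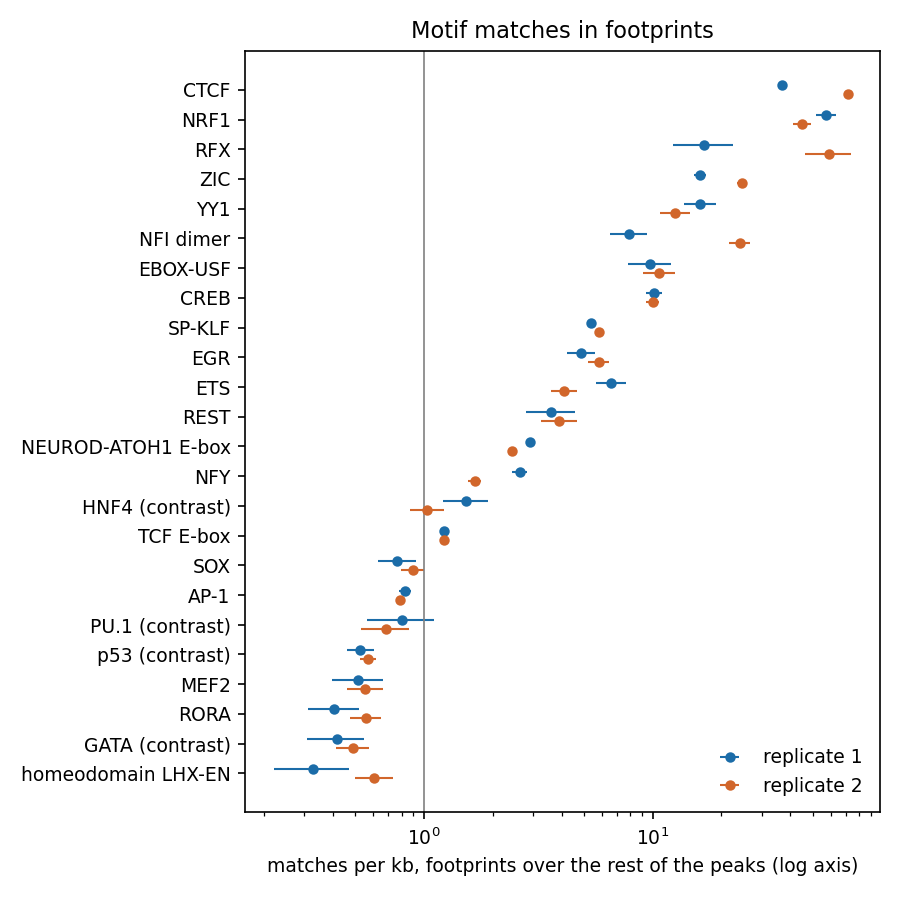
Ratio of motif matches per kb in footprints to those in the rest of the peaks (log axis) for 24 motifs, replicate 1 (blue) and replicate 2 (orange), with exact Poisson 95% intervals of the count in footprints; HNF1 is left out for its low counts. CTCF lay at 36.7 and 71.2, NRF1 at 57.5 and 45.1, and the homeodomain motif at 0.329 and 0.609.

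Footprints with a match were wide for some motifs, but the search itself favours wide footprints, which hold more positions for a match. The median width was 28 and 32 bp for CTCF, 24 and 27 bp for ZIC, 24 and 23 bp for NRF1 and 24 bp in both replicates for CREB. It was 12 and 17 bp for the E-box of NEUROD and ATOH1 and 9 and 13 bp for RORA. Over all footprints the median width was 10 and 11 bp. For the contrast motifs it was 13 and 21.5 bp (HNF4), 12 and 18 bp (p53), 11 and 14 bp (GATA) and 10 and 18 bp (PU.1).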

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

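Alternatives using single gene starts, the shorter peak list for footprints and distal peaks, distal peaks on the X chromosome, promoter peaks for motifs, a motif background from peaks with a footprint and CpG matching for the replicate ratio were chosen after the data were examined, and the others before. No paired analysis was possible because there is 1 group. Ranking footprints by score was not run, since that column is constant. Where no cause is named, the cause was not tested. The share of shared peaks moved to 93.7% and 59.7% with the shorter lists, 98.4% and 58.5% in the stronger 50% of peaks, 77.0% and 44.9% at 50% overlap of both peaks, and 75.1% and 75.7% at equal list length, where the unequal lengths no longer act. The ratio of peak numbers was 1.58 with the shorter lists. The correlation across peaks was 0.811 and 0.954 with pseudocounts of 0.1 and 5, 0.964 for peaks found in both, 0.933 after thinning and 0.935 after scaling by the median ratio. The share more than 2-fold apart was 49.5%, 0.218%, 3.001%, 2.74% and 1.253% in that order. The promoter share was 14.6% and 10.7% with a window of 500 bp, 27.6% and 22.9% with 2500 bp, and 25.3% and 21.02% with the shorter lists. The ratio of X to autosomes in replicate 2 was 0.503 over all peaks, 0.470 for means, 0.533 for promoter peaks found in both and 0.463 for distal peaks. In replicate 1 it was 0.498 for means and between 0.551 and 0.589 in the other settings.

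Without matching on CpG content, 3 lists (housekeeping, activity-regulated and granule neuron) were high in place of 1, at percentiles 95.01 for granule neuron and 97.9 for activity-regulated promoters. Microglia (1.16), liver (1.00) and blood promoters (1.61) became low beside Hox genes, and progenitor promoters moved from percentile 2.34 to 57.1. In the other settings for promoters, 1 list was high and 6 were low, as at first. The numbers listed in both did move. In the stronger 50% of peaks they were 8 of 14 Bergmann glia and astrocyte genes (58.7% of random genes), 6 of 13 interneuron genes (84.4%) and 4 of 15 forebrain genes (89.8%). All 18 granule neuron genes stayed listed. For the replicate ratio, 2 lists (granule neuron and housekeeping) in place of 1 were low with matching on CpG content. For distal peaks 5 or 6 lists were high in every setting. Footprints shared at 50% overlap fell to 39.5% and 19.3%, and inside the shorter peak lists they were 78.7% and 41.5%. Without 1 replicate, the median footprint width was 10 or 11 bp, footprints per peak 2.09 to 2.36 and the share in peaks 82.0% to 86.6%. Between 12 and 15 motifs had a ratio of 2 or more in both replicates, or in the one kept, in all settings run. Against the reversed motif, the motif of SP and KLF was left out, since it reads the same when reversed. The counts also leave out motifs without a match in the background in 1 or both replicates. Of these, CTCF, NFI, NRF1 and RFX stood at 2 or more against the reversed motif, as did RFX in promoter peaks. There the lower bound was used where no ratio exists. With them the counts are 19 and 13. Against the reversed motif, 3 of the 5 contrast motifs were among them, 0 motifs stayed below 1 in both replicates, and the mean ratio turned to 4.29 for MEF2, 2.498 for RORA, 1.86 for AP-1 and 4.79 for p53. That of the TCF E-box turned to 0.653 in promoter peaks. Under these settings 32 values of named promoters moved by more than the spread between the replicates, and the others by less. With a window of 500 bp, C1qc, Erg and Tnnt3 were listed in neither replicate. The mean log2(signal + 1) of Apob fell from 1.75 to 0.319 there. If 1 step stands for 1 read, depth differs 2.27 times between the replicates and may limit which weak peaks are listed.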

Other observations

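The tests with set limits in this part were written down before their results were seen, and the patterns they address were noticed in these data. Not among them were the comparison with peaks listed only in replicate 1 and the ratio of footprints per kb. The GC classes, the matching on GC content and mean signal together, the lower copy limit and the copy search in promoters were not among them either. Some of the densest groups of distal peaks lay around genes of the ZIC family and Neurod2, transcription factor genes of granule cells. Over all protein-coding genes the median was 0.415 distal peaks found in both replicates per 10 kb, and 35 genes had 5 or more. Zic2 and Zic5, neighbours on chromosome 14, had 8.10 and 7.57 per 10 kb, and Zic1 and Zic4, neighbours on chromosome 9, had 6.91 and 6.13, so each pair counts some of its peaks in common. Neurod2 on chromosome 11 had 6.33. Ccr10 and Plekhh3 on chromosome 11 reached 8.48 and 7.19, and Pusl1 and Ints11 on chromosome 4 reached 7.97 and 6.88, with windows that overlap in the same way. Slc22a12 on chromosome 19 and Adam11 on chromosome 11 reached 6.57 and 6.46, above Neurod2. Whether granule cell genes were more frequent than others among the densest was not tested.

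In 4 pairs of genes kept on the X and Y chromosomes, chosen after their values were seen, both members had a promoter peak in both replicates. Kdm6a, a histone demethylase gene on the X, had a promoter signal of 15.6 in replicate 1 and 22.2 in replicate 2, and its Y partner Uty 2.77 and 2.48. Kdm5c had 8.75 and 11.8 and Kdm5d 1.74 and 1.964. Ddx3x had 5.69 and 8.93 and Ddx3y 2.48 and 2.83, and Eif2s3x 5.24 and 8.26 and Eif2s3y 2.34 and 3.33. Of 183 protein-coding genes on the Y, only these 4 Y partners had a promoter peak in both replicates, so the pairs do not stand for the other Y genes. How well reads could be placed on the Y was not examined, so a gene without a listed peak is not shown to have a closed promoter.

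Replicate 2 listed more peaks than replicate 1 and, in the peaks found in both, more footprints per peak. Scaled to the depth of replicate 1, 73.7% of the peaks listed only in replicate 2 lay below the lower quartile of the replicate 1 list, where a difference in depth required at least 50%. Of the peaks listed only in replicate 1, where depth cannot act in this way, 71.5% did too, so this test decides nothing and depth stays open for the number of peaks. Over 121680 pairs of shared peaks the ratio of footprints per peak was 1.41 (2.26 and 3.17 per peak). At equal step counts it fell to 1.02 in the median of 6 classes, from 1.15 in the lowest class to 0.807 in the highest. The peaks of each replicate were classed by their own step counts, so the pairing was not kept. A class thus holds unlike sites of the 2 replicates, 31264 and 12753 peaks in the lowest. Per kb of peak the ratio at equal step counts was 1.13 in the median class and 1.24, 1.21 and 1.19 in the 3 lowest. A difference in depth may therefore account for a part of the difference in footprints, and a part per kb remains in the weaker peaks. The depth itself was read from the signal steps, and no biological explanation was tested, since both libraries belong to 1 group.

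Promoter peaks had higher ratios of replicate 2 to replicate 1 than distal peaks, with median log2 ratios of 0.66 and 0.28 among shared peaks with at least 100 steps in both. When distal peaks were matched to promoter peaks on GC content, the difference turned to -12.8% of its size, and when they were matched on mean signal, 64.2% remained. A candidate explanation is a GC-dependent difference between the libraries, since the median log2 ratio of promoter and distal peaks was -0.15 and 0.10 in the lowest of 10 GC classes and 1.00 and 0.99 in the highest. For the strength of the peaks alone, 64.2% lies between the limits set for that test. Matched on GC content and mean signal together, the difference turned to -19.1% of its size. No excess was thus left for strength to account for once GC content was matched. A part that strength shares with GC content cannot be told apart from it. No biological explanation was tested.

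The 10 strongest distal peaks found in both replicates were searched for sequence that occurs in many copies. A sequence of 36 bases present 5 times or more was found in 2 of the 10, those on chromosome 8 from 20122145 and in Lars2, and in 1 of 100 random distal peaks. Reads shared between near-identical copies could thus raise some of these signals, but 2 of 10 lies between the limits set for the test, and copies missing from the reference were not counted. At 2 copies or more the numbers were 4 of 10 and 3 of 100. Among the 20 promoters with the largest fold between the replicates, those of Hist1h2bh, Gm11168 and Gm10719 held one.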
